A study of Mus musculus with 7 samples.

How the data were processed

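Total RNA of cells purified by flow sorting from mouse skin at postnatal day 50 was sequenced in 7 libraries: Koa ear epidermis, WT ear epidermis, WT dorsal epidermis, Koa ear dermis, WT ear dermis, WT dorsal dermis and WT tail dermis. Each group had 1 library. The strain label names CD1 and C3H. The series also holds histone mark, CTCF and chromatin contact data, which were not analysed here.

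The deposited values are FPKM (fragments per kilobase of transcript, scaled by mapped fragments), computed by the authors. Per the submitters' processing notes, TopHat2 2.0.13 and Cufflinks 2.2.1 were used with the builds GRCm38 and mm9. The notes give neither the role of each build nor the gene annotation. The table holds 22552 gene symbols, of which 22290 were matched by symbol to a RefSeq annotation of GRCm38, the source of all printed positions. No symbol occurs more than once, 2039 symbols stand at 0 in all libraries and 733 are short RNAs. The names of 2 columns are misspelled and were matched to samples by title. The tail column was made in another way than the others: its values carry at most 2 decimals, and 222 symbols at 10 FPKM or more in the other 6 libraries are listed at 0 in it. Col1a1, Col1a2 and Col3a1 are listed at 0 in dermal libraries, as failed estimates of very abundant genes would be (Col1a1 stands at 4362 FPKM in WT ear dermis), and these 3 genes were left out of counts and lists.

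Differences between libraries were taken on the log2(FPKM + 1) scale. In each of 11 comparisons of 2 libraries, genes with at least 1 FPKM in 1 of them were kept, and genes that differed by at least 1 on that scale were counted as higher or lower. With 1 library per group no test and no p-value can be given. Of each of 38 lists of gene families, positional genes, signalling genes and cell type markers, the median difference over expressed members was set beside 10000 random lists of the same size, drawn from genes in the same 10 classes of mean expression. The percentile among them is a description of these libraries, and lists with fewer than 3 expressed members were not described. The lists, the pseudocount, the filter, the size rule, the comparisons and the naming rule were chosen before the data were examined.

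The genes named in the text come from a rule: every Hoxc gene, the 8 genes furthest apart in each direction with at least 5 FPKM in 1 of the 2 libraries, and up to 4 members of each list with the widest differences, or more where members went both ways. By this rule the 8 genes were mostly short RNAs, whose FPKM is unstable because of their length: 8 of 8 in each direction between Koa and WT ear dermis, and between 3 and 8 of 8 elsewhere. The next genes that are not short RNAs are given in their place, a choice made after the data were seen. In that order Cwc22, Gm10136 and the histocompatibility genes were named. Further genes were singled out after their values were seen: Ndp, Krt71 between Koa ear and dorsal epidermis, the genes named for the overlap of dermis and epidermis, and those given at the end for class I histocompatibility, clock and growing hair. Some genes that the rule gives are not reported here. A list of 13 clock output genes and a list of 5 clock activators were added after the data were seen.

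The depth of 6 libraries was recovered from their FPKM values. A short RNA, or a gene under 0.5 FPKM, with a whole number of fragments leaves steps in the values. In the libraries set against WT ear dermis, 47.3% to 54.2% of the values compared lay on these steps. A fit over 423 genes gave a length offset of 207 nt. The depths, in mega fragments (M), were 35.6 M for Koa ear dermis, 36.4 M for WT ear dermis, 32.4 M for WT dorsal dermis, 35.4 M for Koa ear epidermis, 40.4 M for WT ear epidermis and 31.7 M for WT dorsal epidermis. The tail library, rounded to 2 decimals, allows no such recovery. Tested on simulated data, the procedure returned all 6 simulated depths. The simulated values came from whole counts for every gene, which the deposited estimates need not do. For the Hoxc genes, FPKM was turned into fragments with these depths and the longest transcript, and ratios carry exact 95% intervals of counting error, which do not cover variation between animals.

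Counting error alone at these depths put 0 of 11874 genes past the size rule between Koa and WT ear dermis, where 223 of them passed it in the data. It also put 0 past the rule in the other 5 comparisons among ears and back of the same layer. Short RNAs and genes with short transcripts were left out of these draws, so the draws do not cover them. The draws also hold no variation between animals or library preparations. The genes past the rule in the data are therefore not shown to exceed such variation. Tested on simulated data, the size rule returned 84% to 92% of genes changed by 2.5 times and 99% to 100% of those changed by 4 times. Of 200 simulated lists without a shift, 1.5% fell outside the central 95% of random lists, and of lists shifted by 1 on the log2 scale, 100% did. These lists were drawn gene by gene without matching on expression, and shifts smaller than 1 were not simulated.

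The share of epidermal RNA in each dermal library was taken as the median level of 8 keratinocyte markers in percent of the epidermal library of the same genotype and position. These are the genes of the basal keratinocyte list, and Krtdap among them is also on the suprabasal list. In 1 alternative that share of the epidermal profile was subtracted and the rest rescaled, which by construction brings the dermal levels of the basal list towards 0. Genes that fell under 1 FPKM by it left the lists, so some medians after the subtraction rest on fewer genes. For contrasts that share a library, covariance across genes was compared with simulations in which Koa has no effect and the libraries are equally noisy. For contrasts that share none, counts of common genes were set beside the number that independent lists would share. Other alternatives were pseudocounts of 0.1 and 5, no filter or a filter of 5 FPKM, rescaling by median ratios, rescaling to the same total, another choice among repeated symbols, and leaving out the short RNAs, the Hox genes with the marker lists, or genes at 0 in the tail library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.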

Results

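RNA was measured by sequencing in skin cells of mice at postnatal day 50, in 7 libraries from 7 groups, each with 1 library. The cells had been sorted from the dermis, the deeper layer of skin built by fibroblasts, or from the epidermis, the outer layer of keratinocytes. Ear dermis and ear epidermis came from wild-type (WT) mice and from mice with 1 copy of the Koa allele, a dominant allele with an inversion on distal chromosome 15 and hairy ears. Dorsal dermis, dorsal epidermis and tail dermis came from WT mice. No group had a replicate, so no difference has a replicate check and no test between conditions was made.

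The depth recovered from the values lay between 31.7 and 40.4 M fragments in 6 libraries, and is unknown for the tail library. Between 11600 and 13592 genes per library stood at 1 FPKM or more. Xist, transcribed from the inactive X chromosome of females, stood at 41.5 FPKM in the tail library and at most 0.122 FPKM in the other 6. The Y-linked gene Ddx3y was listed at 0 in the tail library and lay between 33.1 and 38.3 FPKM in the others.

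The first question was what the Koa allele changes in the dermis of the ear. Genes of the Hoxc cluster, transcription factors that mark position along the body, were near the floor in WT ear dermis and higher in Koa ear dermis. Hoxc8 stood at 10.2 FPKM in Koa and 0.241 FPKM in WT ear dermis, a ratio of 42.3 with an exact 95% counting interval of 26.1 to 70.6. The ratio was 25.1 (10.2 to 100.4) for Hoxc4, 34.3 (8.98 to 285) for Hoxc6 and 10.1 (4.80 to 21.6) for Hoxc9. Keratins of the growing hair follicle were also higher, and products of mast cells were lower.

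The Hoxc cluster lies on chromosome 15 from 102921131 to 103036856 (GRCm38, positions of the 9 genes taken from the reference annotation). Of its genes, 5 reached 1 FPKM in either ear dermis, 4 passed the size rule (a difference of at least 1 on the log2(FPKM + 1) scale), all of them higher in Koa, and the median difference was 1.26. Hoxc5 stood at 1.56 against 0.0109 FPKM, the latter about 1 fragment, so its ratio of 143 has an interval of 27.3 to 6142. The 5' genes of the cluster stayed low: Hoxc10 stood at 0.0493 FPKM in Koa and 0.0804 FPKM in WT, Hoxc12 at 0.0440 and 0.172 FPKM, and Hoxc11 was listed at 0 in Koa and stood at 0.0386 FPKM in WT. Hoxc13, a factor of the hair shaft, stood at 0.983 and 0.345 FPKM, a ratio of 2.85 (1.85 to 4.62). In the matching epidermal libraries Hoxc13 stood at 10.3 and 6.52 FPKM. Epidermal RNA at the median marker shares given below (11.6% and 6.26%) could give both dermal levels. The intervals cover counting error only. Among genes beside the cluster, none of the 16 expressed neighbours passed the size rule (median 0.06), nor did any of the 7 expressed genes at Trps1 on the same chromosome (median -0.04), where Trps1 itself stood at 8.34 and 7.39 FPKM. Of the other 3 Hox clusters fewer than 3 genes each reached 1 FPKM. Hoxa2 stood at 18.7 FPKM in Koa and 19.3 FPKM in WT.

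**Figure D1:**
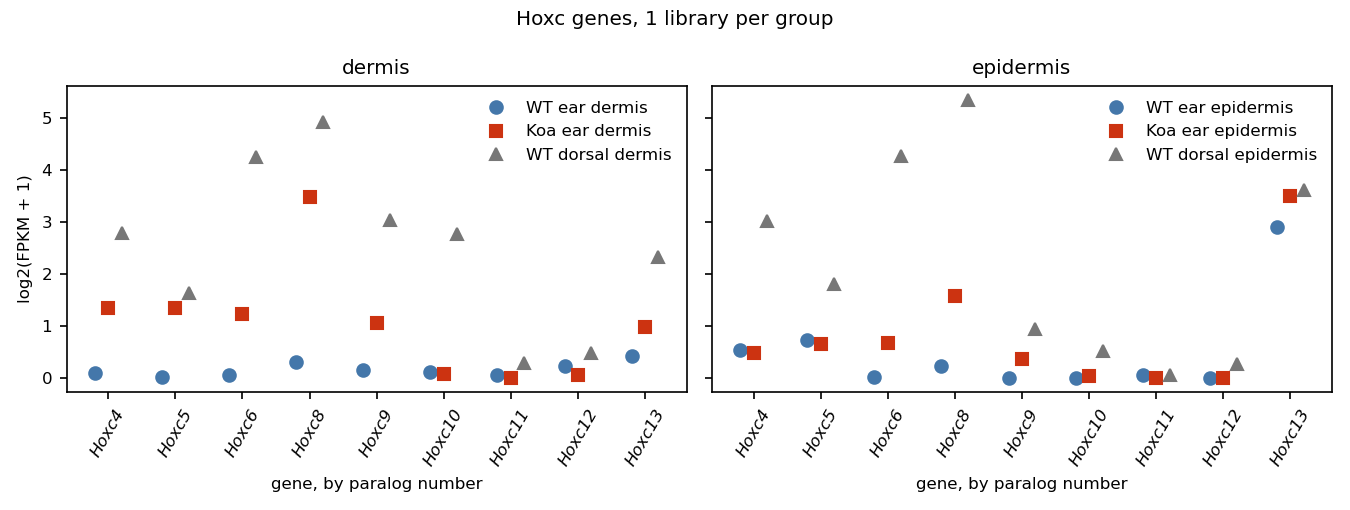
Levels of the 9 Hoxc genes (x axis) as log2(FPKM + 1) (y axis) in dermis and epidermis, with 1 point per library for WT ear, Koa ear and WT dorsal skin. In dermis Hoxc8 stood at 0.241, 10.2 and 29.5 FPKM in that order, while Hoxc10 stood at 0.0804, 0.0493 and 5.80 FPKM.

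Lists of genes are said to stand apart where their median lies outside the central 95% of random lists of like expression, a description of these libraries. Over all comparisons 233 of 405 list medians did. Random lists hold genes drawn independently, whereas members of a list can vary together, which the percentile does not take into account. Of the growing hair follicle list, 6 of the 9 expressed genes were higher in Koa ear dermis and none lower, with a median of 1.76. Krt25 and Krt71, keratins of the inner root sheath, stood at 9.94 and 8.25 FPKM in Koa against 0.0190 and 0.0279 FPKM in WT. Krt35, a keratin of the hair shaft, stood at 6.52 against 0.0362 FPKM, and Tchh, the inner root sheath protein trichohyalin, at 8.16 against 0.987 FPKM. Keratinocyte markers moved with this group. Basal keratinocyte markers had a median of 1.17 (5 of 8 higher), which came to 0.00 for these 8 genes once the keratinocyte share given next was subtracted, and to -0.60 for the 5 still at 1 FPKM. The share was taken from these same 8 genes, so this fall was set by the procedure and tells nothing of its cause. Krt5 stood at 787 against 267 FPKM. Suprabasal markers had a median of 1.30 (4 of 7 higher), with Krt10 at 346 against 94.7 FPKM, and with that share subtracted the median of the 7 was 0.00, and 3.20 for the 3 still at 1 FPKM. The 8 basal markers stood in Koa ear dermis at a median of 11.6% of their level in Koa ear epidermis, and in WT ear dermis at 6.26% of theirs. With that share of the epidermal profile subtracted from each dermal library, the hair follicle median was 1.98 (1.43 with the genes that fell under 1 FPKM kept) and the Hoxc median 1.38. Growing hair genes stood at a median of 25.9% of Koa ear epidermis, 7 of 9 above the highest marker (13.9%). A share set by basal markers therefore cannot decide whether these hair genes came from follicle epithelium in the dermal library.

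**Figure D2:**
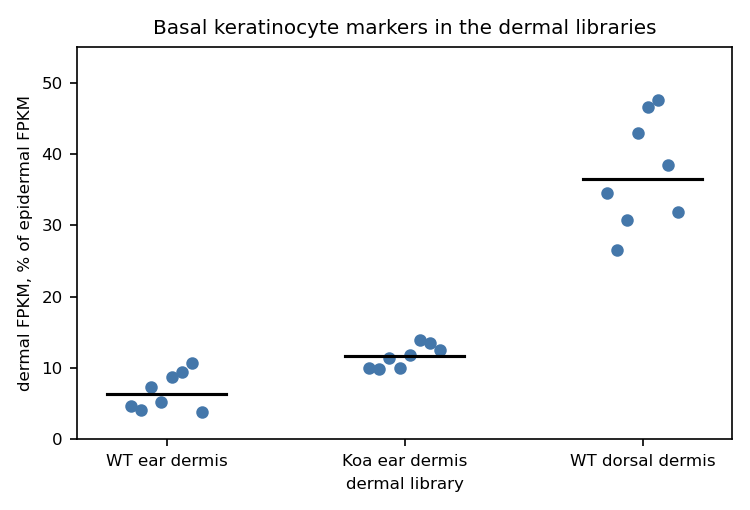
Level of each of 8 markers of the basal keratinocyte list, of which Krtdap is also on the suprabasal list, in a dermal library (points) as percent of its level in the epidermal library of the same genotype and position (y axis), for 3 dermal libraries (x axis), with lines at the medians. The medians are 6.26% in WT ear, 11.6% in Koa ear and 36.5% in WT dorsal dermis, where markers run from 26.5% to 47.6%.

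Dermal papilla markers, genes of the fibroblast cluster at the base of the hair follicle, had a median of 0.26, and 3 of 17 were higher by the size rule. These were Bmp4, a BMP ligand (47.7 against 21.5 FPKM), and the retinoid-binding proteins Crabp1 (112 against 52.7 FPKM) and Crabp2 (9.17 against 4.03 FPKM). Lef1, a partner of beta-catenin, stood at 5.95 and 2.62 FPKM, and Ndp, a ligand of the Wnt receptor Fzd4, at 7.84 and 14 FPKM. Among Wnt ligands and R-spondins the median was 0.32, with 1 of 17 past the size rule, Rspo1 (43.4 against 20.1 FPKM). Wnt target genes had a median of 0.23 with none past the size rule, and this median did not stand apart at a pseudocount of 5 or after the subtraction of the keratinocyte share (0.10). Secreted Wnt inhibitors did not stand apart (median 0.16), but did after the subtraction (0.24), at either other pseudocount, under either other filter and with equal totals, and their 1 gene past the rule, Sfrp2, was lower in Koa (59.9 against 132 FPKM). BMP antagonists did not stand apart as a list (median 0.11), but Grem1, a secreted BMP antagonist, stood at 8.50 against 0.900 FPKM. BMP and TGF-beta ligands had a median of 0.06, with Bmp4 and Inhba (12.7 against 5.39 FPKM) higher. Other medians outside the central 95% belonged to dermal sheath and smooth muscle (0.35), fibroblast matrix (0.18) and cell cycle genes (0.21), none with a gene past the size rule, and the last no longer stood apart after the subtraction (0.13).

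Mast cell genes were lower in Koa ear dermis, 5 of 6, with a median of -1.22. The chymase Cma1 stood at 30.7 against 124 FPKM, the mast cell protease Mcpt4 at 53.3 against 140.1 FPKM, and carboxypeptidase Cpa3 at 36.5 against 87.7 FPKM. T cell and Langerhans cell markers had a median of 0.79, and the T cell receptor component Cd3g stood at 62.1 against 23.6 FPKM. Schwann cell markers had a median of 0.56, with the neurotrophin receptor Ngfr at 7.16 against 2.30 FPKM. Melanocyte markers had a median of 0.36, red blood cell genes -0.46 and stress genes 0.31. Myeloid markers went both ways around a median of -0.19, which stood apart before the subtraction and not after (-0.11): Cd68 stood at 59.5 against 125 FPKM, and Itgam at 9.97 against 5.68 FPKM. Not standing apart were cartilage (0.02), fibroblast (0.10), adipocyte (0.21), skeletal muscle (0.07), endothelium (0.08), pericyte (0.00), BMP targets (0.04) and growth factors (-0.06), of which adipocyte genes did with equal totals. Hair follicle stem cell genes (0.03, turning to -0.29), sebaceous gland genes (-0.14, then -0.31) and other positional factors (0.10, then 0.15) stood apart only after the subtraction.

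Outside the lists, the genes furthest apart included Slc26a7, an anion transporter (30.2 FPKM in Koa, 1.71 in WT), Retnla, a secreted product of alternatively activated macrophages (26.3 and 1.53 FPKM), the splicing factor Cwc22 (108 and 12.6 FPKM) and Gfap, an intermediate filament of glia (11.1 and 0.720 FPKM). Furthest the other way were the histocompatibility genes H2-Ea-ps (24.7 and 419.8 FPKM), H2-Eb1 (12.5 and 171 FPKM) and H2-T9 (0.00562 and 12 FPKM), then Gm10136 (3.09 and 48.8 FPKM), the tryptase Tpsab1 (5.01 and 42 FPKM), Ifi202b (12.5 and 93.7 FPKM), the chemokine Ccl3 (0.576 and 6.42 FPKM) and Wfdc2 (8.92 and 40.3 FPKM). Histocompatibility genes have close paralogs, between which reads can be divided, so their single values are uncertain. In all, 234 genes were higher and 146 lower of 13690, or 183 and 78 without short RNAs. The count depends on the pseudocount, with 681 genes past the rule at a pseudocount of 0.1 and 185 at 5.

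The same question in ear epidermis gave hair follicle genes first. Of 13 expressed genes of the growing follicle, 8 were higher in Koa ear epidermis and none lower, with a median of 1.80. Krt71 stood at 31.9 FPKM in Koa and 0.930 FPKM in WT, Krt25 at 33.3 and 1.88 FPKM, Krt35 at 28.2 and 1.91 FPKM, and Krt31 at 8.69 and 0.917 FPKM. Outside the list the hair keratins Krt75 (22.2 and 0.743 FPKM) and Krt85 (16.9 and 0.798 FPKM), the keratin-associated protein gene Krtap7-1 (12.7 and 0.237 FPKM), the gap junction gene Gjb2 (45 and 1.96 FPKM) and the peptide transporter Slc15a2 (10.2 and 0.0195 FPKM) were among the 8 furthest apart. Hoxc8 stood at 1.97 against 0.171 FPKM, a ratio of 11.5 (6.62 to 21.5).

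Apart from Hoxc8 and Hoxc13, the Hoxc genes stood under 1 FPKM in ear epidermis of either genotype. Hoxc6 stood at 0.590 against 0.0178 FPKM, the latter about 1 fragment, with a ratio of 33.1 (5.48 to 1351). Hoxc9 stood at 0.279 FPKM in Koa and was listed at 0 in WT. Hoxc4 stood at 0.397 and 0.445 FPKM, Hoxc5 at 0.570 and 0.656 FPKM, and Hoxc13 at 10.3 and 6.52 FPKM, a ratio of 1.58 (1.41 to 1.75). Hoxc10 stood at 0.0330 FPKM in Koa and was listed at 0 in WT, Hoxc11 was listed at 0 in Koa and stood at 0.0348 FPKM in WT, and Hoxc12 was listed at 0 in both. The 4 expressed Hoxa genes had a median of -0.02, the Hoxc neighbours 0.01 and the Trps1 group 0.01, with no gene past the size rule in any of them.

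Hair follicle stem cell genes had a median of 0.24, with Lgr5, a stem cell receptor for R-spondins (13.2 against 5.78 FPKM), and Cd34 (21.9 against 10.4 FPKM) higher. Basal and suprabasal keratinocyte markers had medians of 0.38 and 0.37 with none past the size rule. Cell cycle genes (-0.41, with Birc5 at 29 against 46.2 FPKM) and sebaceous gland genes (-0.36, with Mgst1 at 245 against 477 FPKM) had medians below 0, again with none past the rule. Of 3 expressed adipocyte genes the median was -0.61, but the 1 gene past the size rule, Fabp4, was higher in Koa (1.32). BMP antagonists (0.47, none past the rule) and secreted Wnt inhibitors (0.45, none past the rule) stood apart upward, the former not without the filter on low values, while Wnt ligands (0.15) and Wnt targets (0.10) did not. Fibroblast matrix genes moved the same way (0.46, with Fn1 at 9.13 against 3.71 FPKM), as did fibroblast (0.57) and myeloid markers (0.77), of which these last lists no longer stood apart without the filter on low values. Stress genes had a median of 0.14.

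Lower in Koa ear epidermis were Gm10136 (2.28 against 108 FPKM), H2-T9 (8.28e-05 against 8 FPKM), the hydroxypyruvate isomerase gene Hyi (4.50 against 26.8 FPKM), the protease inhibitor Slpi (4.03 against 18.4 FPKM), Cox7b of the respiratory chain (91.2 against 324 FPKM), Snhg3 (72.9 against 247 FPKM), Hsd11b1 (1.41 against 6.78 FPKM) and Lbp (1.41 against 6.75 FPKM). In total 259 genes were higher and 103 lower of 12062, or 189 and 63 without short RNAs. At a pseudocount of 0.1 the count was 680, and at 5 it was 170.

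The Koa differences of dermis and epidermis share no library. Without short RNAs, 42 genes were higher in Koa in both layers where lists drawn independently from the 11363 genes would share 1.70, and 16 were lower in both against 0.210. Among the 42 were Krt25, Krt71, Krt35, Hoxc8 and Cwc22, and among the 16 were Gm10136, H2-T9 and Hyi. Koa ear dermis also holds more epidermal RNA than WT ear dermis (11.6% against 6.26%), which alone can put epidermal genes on both lists, and the numbers for independent lists take no account of it. The animals behind these libraries are not known to differ in the Koa allele alone.

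A second question was how the dermis of the back differs from that of the ear. Hox genes were higher in dorsal dermis in 3 clusters, and cartilage genes were lower. Hoxc8 stood at 29.5 FPKM in dorsal and 0.241 FPKM in ear dermis, Hoxc6 at 18 and 0.0396 FPKM, and Hoxa5 at 15 and 0.0328 FPKM. The cartilage matrix gene Chad stood at 1.73 FPKM in dorsal and 257 FPKM in ear dermis. Keratinocyte markers stood in dorsal dermis at a median of 36.5% of their epidermal level, against 6.26% in ear dermis, and the stress genes were all higher in dorsal dermis.

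Of the expressed Hoxc genes 7 of 7 were higher in dorsal dermis (median 2.70), of the Hoxb genes 8 of 9 (median 2.47) and of the Hoxa genes 6 of 7 (median 1.62). Hoxc9 stood at 7.24 against 0.109 FPKM, Hoxc4 at 5.90 against 0.0618 FPKM, Hoxc10 at 5.80 against 0.0804 FPKM, Hoxc5 at 2.09 against 0.0109 FPKM, and Hoxc13 at 4 against 0.345 FPKM. Hoxc11 (0.217 and 0.0386 FPKM) and Hoxc12 (0.387 and 0.172 FPKM) were low at both positions. Of the Hoxb cluster (chromosome 11, 96194316 to 96368254), Hoxb2 stood at 11.4 against 0.771 FPKM, Hoxb6 at 6.22 against 0.0246 FPKM, Hoxb7 at 5.77 against 0.0516 FPKM and Hoxb8 at 5.58 against 0.0225 FPKM. In the Hoxa cluster (chromosome 6, 52155367 to 52260880), Hoxa7 stood at 10.1 against 0.157 FPKM, while Hoxa2 went the other way, at 2.61 in dorsal and 19.3 FPKM in ear dermis. The 3 expressed Hoxd genes (chromosome 2, 74668225 to 74765142) had a median of 0.88, which stood apart only without the filter on low values or after the subtraction of the keratinocyte share (0.99). After the subtraction the other medians were 1.45 for Hoxa, 1.20 for Hoxb and 3.30 for Hoxc (0.75, 0.99 and 3.19 with the genes that fell under 1 FPKM kept), and Hoxc13 no longer differed (0.00).

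**Figure D3:**
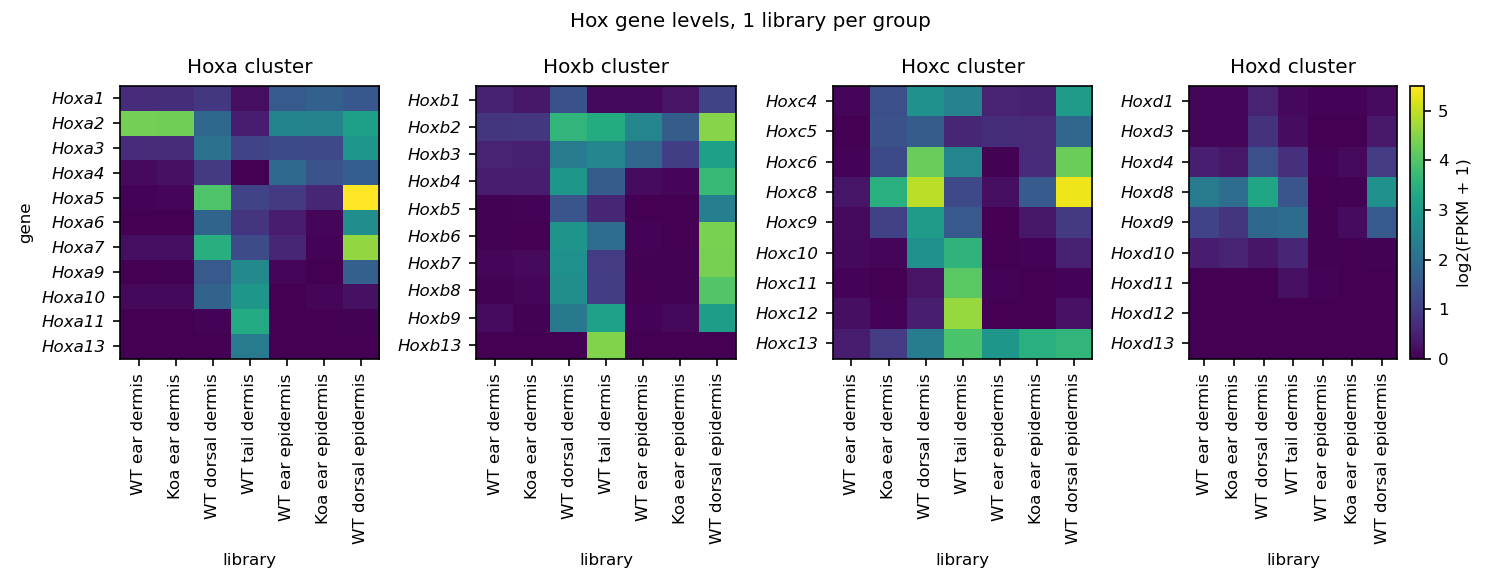
Levels of the Hox genes of 4 clusters (y axis, ordered by paralog number) in each of 7 libraries (x axis), coloured by log2(FPKM + 1). The tail library holds the 5' genes Hoxc12 (24 FPKM) and Hoxb13 (20.8 FPKM), and both ear dermis libraries hold Hoxa2 (19.3 FPKM in WT and 18.7 FPKM in Koa).

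Other transcription factors of position went both ways, 5 higher and 6 lower of 22, and their median of -0.58 no longer stood apart after the subtraction (-0.05). En1 stood at 6.24 FPKM in dorsal and 0.0467 FPKM in ear dermis, and Zic1 at 5.10 and 0.236 FPKM. The distal-less factor Dlx6 stood at 0.463 and 15.1 FPKM, and Prrx2 at 8.55 and 58.2 FPKM. Cartilage genes were lower in dorsal dermis, 14 of 15, with a median of -3.42. Cytl1 stood at 3.61 against 354 FPKM, Ucma at 0.755 against 127 FPKM, and the collagen gene Col9a1 at 0.277 against 49.4 FPKM. Outside the lists, Angptl7 (11.6 against 1310.5 FPKM), the collagen gene Col8a1 (8.43 against 791 FPKM), the proteoglycan fibromodulin (Fmod, 11.2 against 624 FPKM) and Cilp2 (0.356 against 59.7 FPKM) were lower. Fibroblast matrix genes had a median of -0.95, with 7 of 15 lower, among them tenascin C (Tnc, 5.40 against 117 FPKM) and periostin (Postn, 494 against 2088 FPKM). After the subtraction of the keratinocyte share the matrix median (-0.40) no longer stood apart.

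Signalling genes moved in both directions. Secreted Wnt inhibitors had a median of -1.41, with 5 lower and 3 higher of 10. Wif1 stood at 25.6 in dorsal and 218 FPKM in ear dermis, Frzb at 0.625 and 10.6 FPKM, Sfrp2 at 26.4 and 132 FPKM, and Sfrp4, the other way, at 24 and 1.45 FPKM. Dermal papilla markers had a median of -0.45, which no longer stood apart after the subtraction (-0.08). Bmp5, which is known for its part in ear cartilage, stood at 3.27 against 70.3 FPKM, Grem1 at 12.7 against 0.900 FPKM and the growth factor Igf2 at 3.01 against 116 FPKM. Wnt targets (0.02), BMP ligands (-0.30) and BMP antagonists (0.52) did not stand apart as lists, the last pair except at a filter of 5 FPKM. BMP targets (0.27), Wnt ligands (0.05) and growth factors (-0.25) did not before the subtraction and did after, at -1.03, -0.61 and -0.62 (-0.65, -0.42 and -0.62 with the genes that fell under 1 FPKM kept), so BMP targets and Wnt ligands turned direction. The growth factors also stood apart at a filter of 5 FPKM.

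All 13 stress genes, immediate early and heat shock genes known to respond to cell dissociation, were higher in dorsal dermis (median 3.48, and 2.51 with the keratinocyte share subtracted). Fosb stood at 259 against 7.91 FPKM, and Atf3 at 642 against 8.17 FPKM, a difference of 6.13 that turned to -0.49 with the share subtracted. Basal keratinocyte markers had a median of 2.74 (8 of 8 higher, Krt5 at 2377 against 267 FPKM), suprabasal markers 3.65 and growing hair follicle genes 1.64. With the share subtracted and every gene kept these came to 0.04, 0.00 and 0.90. For the basal markers, from which the share was taken, this fall was set by the procedure. Krt77, an epidermal keratin, stood at 549 against 1.34 FPKM (7.30 with the share subtracted). The growth factor Epgn (79 against 0.128 FPKM) turned to -0.09 and the prostaglandin synthase Ptgs2 (45.3 against 0.467 FPKM) to -0.47, and the epithelial gene Sfn (553 against 16.6 FPKM) came to 0.00. T cell and Langerhans cell markers were higher (1.75, 7 of 8) and mast cell genes lower (-2.23, 5 of 6), as were pericyte markers (-1.23, 4 of 6). Red blood cell genes (1.61) and hair follicle stem cell genes (0.71) also stood apart, and the stem cell median turned to -1.24 after the subtraction (-0.86 with the genes that fell under 1 FPKM kept). Cell cycle genes (0.65) and sebaceous genes (-0.52) no longer stood apart after it (0.13 and -0.55), nor did dermal sheath and smooth muscle (0.65) at a filter of 5 FPKM. The counts were 1670 higher and 1004 lower of 14234. Rescaling each library to the same total moved the median of all genes from -0.05 to -0.26 and turned the split to 1580 higher and 1896 lower, and a pseudocount of 5 left 1277 genes past the rule. The subtraction itself moved the median of all genes to -0.22.

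Koa ear dermis was then set beside WT dorsal dermis, to see what still parts them. The Hoxc genes were lower in Koa ear, 6 of 7 with a median of -1.45. Hoxc8 in Koa ear dermis stood at 0.345 times its dorsal level (0.317 to 0.376), Hoxc5 at 0.745 times (0.598 to 0.931), Hoxc4 at 0.262 times (0.208 to 0.325), Hoxc9 at 0.151 times (0.118 to 0.190) and Hoxc6 at 0.0752 times (0.0573 to 0.0962). Hoxb genes, 9 of 9 lower (median -2.47), and Hoxa genes, 6 of 7 lower (median -1.62), went the same way, and with the keratinocyte share subtracted these medians were -1.34 and -1.41, or -1.02 and -0.75 with the genes that fell under 1 FPKM kept. As deposited, Hoxa5 stood at 0.0672 against 15 FPKM and Hoxb6 was listed at 0 in Koa ear against 6.22 FPKM. Cartilage genes were higher in Koa ear, 14 of 15 (median 3.51), with Cytl1 at 496 against 3.61 FPKM, Chad at 259.5 against 1.73 FPKM and Ucma at 151 against 0.755 FPKM. Angptl7 (990.5 against 11.6 FPKM), Col8a1 (635 against 8.43 FPKM), Col9a1 (51 against 0.277 FPKM) and Cilp2 (49.6 against 0.356 FPKM) were higher too. Krt2, an epidermal keratin, stood at 302 against 1.92 FPKM, a difference of 6.70 that shrank to 1.78 with the keratinocyte share subtracted.

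Basal keratinocyte markers (-1.58) and stress genes (-2.99, 13 of 13 lower) moved with this contrast, and Krt77 stood at 3.04 against 549 FPKM. With the share subtracted the basal median was -0.34 with every gene kept, and -1.49 for the 5 genes still at 1 FPKM. The share was taken from the basal markers themselves, so the shrinkage of their median was set by the procedure. Cxcl10 (0.982 against 59.1 FPKM), the complement gene C6 (0.181 against 30.5 FPKM) and Gm10136 (3.09 against 108 FPKM, -2.56 with the share subtracted) were lower in Koa ear. Some genes lower there turned the other way once the keratinocyte share was subtracted: Epgn (from -5.94 to 0.03), Atf3 (from -5.57 to 0.80), Ptgs2 (from -4.93 to 0.34) and Ch25h (from -4.57 to 0.72). Growing hair follicle genes did not stand apart between the Koa ear and the back (-0.21) before the keratinocyte share was subtracted and did, upward, after it (0.92, or 0.53 with the genes that fell under 1 FPKM kept) or at a filter of 5 FPKM. Wnt ligands (0.12, then 1.04), Wnt targets (0.17, then 0.60) and BMP targets (-0.09, turning to 1.05, or 0.75 with the genes that fell under 1 FPKM kept) also stood apart only after the subtraction. Secreted Wnt inhibitors (1.14), dermal papilla markers (0.72) and fibroblast matrix genes (0.77) were higher as lists in Koa ear, the matrix genes no longer so after the subtraction (0.30). Pericyte markers (1.05) and mast cell genes (0.97) stood apart before the subtraction and not after (0.61 and 0.52). A total of 845 genes were higher and 1370 lower of 14223. Rescaled to the same total, the split was 1674 and 1323 with the median of all genes at 0.29 (0.20 after the subtraction), and a pseudocount of 5 left 1050 genes past the rule.

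Koa minus WT ear and dorsal minus ear share the WT ear library. Across 14388 genes, which are not independent replicates, their covariance was 0.207, where simulation with no Koa effect gave 0.159, and the correlation across genes was 0.358. The shared library alone makes a correlation above 0, and no value without a Koa effect was drawn for it. The simulation took its noise from the spread of Koa minus WT ear itself, with the libraries equally noisy. A noisier WT ear library would raise the covariance with no Koa effect. The gap between 0.207 and 0.159 therefore does not decide whether Koa ear dermis moved towards dorsal dermis. With the keratinocyte share subtracted and short RNAs left out (13754 genes), the covariance was 0.121 against 0.0682. How much of this fall belongs to either step was not separated.

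The epidermis of back and ear differed by Hox genes as well. Of the expressed Hoxb genes 8 of 9 were higher in dorsal epidermis (median 3.01), of the Hoxc genes 4 of 5 (median 2.48) and of the Hoxa genes 5 of 8 (median 1.63). Hoxa5 stood at 44.9 FPKM in dorsal and 0.917 FPKM in ear epidermis, Hoxc8 at 39.8 and 0.171 FPKM, Hoxb7 at 19.8 and 0.0232 FPKM, and Hoxb6 at 19.9 and 0.0443 FPKM. The ear-high genes were led by Krt2 (9.40 in dorsal and 3174 FPKM in ear epidermis), with the homeobox genes Tlx1 (0.0864 and 37.3 FPKM) and Otx1 (0.253 and 14.4 FPKM) and the IGF-binding protein Igfbp2 (3.85 and 177 FPKM).

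Hoxc6 stood at 18.3 FPKM in dorsal and 0.0178 FPKM in ear epidermis, Hoxc4 at 7.08 and 0.445 FPKM, Hoxc5 at 2.52 and 0.656 FPKM, and Hoxc13 at 11.2 and 6.52 FPKM. Hoxc9 (0.917 FPKM), Hoxc10 (0.425 FPKM) and Hoxc12 (0.198 FPKM) were low in dorsal epidermis and listed at 0 in the ear, and Hoxc11 stood at 0.0444 and 0.0348 FPKM. Hoxc9 and Hoxc10 were thus at 7.24 and 5.80 FPKM in dorsal dermis but under 1 FPKM in dorsal epidermis.

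Stress genes were higher in dorsal epidermis too, 13 of 13 with a median of 3.30, Atf3 at 1749.8 against 22.7 FPKM and Nr4a1 at 915 against 11.8 FPKM. With them moved Epgn (295 against 1.04 FPKM), the sterol enzyme gene Ch25h (175 against 0.431 FPKM), the prostaglandin synthase Ptgs2 (146 against 1.64 FPKM) and the EGF receptor ligand Areg (77.7 against 0.473 FPKM). BMP antagonists had a median of 1.28 (5 of 7 higher), with follistatin (Fst) at 142 against 25.6 FPKM and Grem1 at 19.1 against 2.38 FPKM. BMP ligands (0.77), Wnt ligands (0.92, with Wnt3 at 34.2 against 5.66 FPKM), growth factors (0.86) and secreted Wnt inhibitors (0.87) stood apart upward, the growth factors not without the filter on low values and the Wnt inhibitors not at a filter of 5 FPKM. Hair follicle stem cell genes had a median of 1.12 (6 of 10 higher, Cd34 at 65.9 against 10.4 FPKM and Lhx2 at 72.3 against 19.4 FPKM), growing hair follicle genes 0.67 (not standing apart at a pseudocount of 5, Shh at 4.25 against 0.0703 FPKM) and suprabasal markers 1.03. Dermal papilla markers had a median of 1.34, from lower levels than in dermis, and fibroblast markers stood in dorsal epidermis at 0.485% of their dermal level, against 0.197% in ear epidermis.

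Sebaceous gland genes were lower in dorsal epidermis, 5 of 9 (median -1.61), with the fatty acid desaturase Scd1 at 61.8 against 539.7 FPKM and Pparg at 2.72 against 34.7 FPKM. Cell cycle genes had a median of -0.83, with Mki67 at 20.4 against 52.2 FPKM. In total 1432 genes were higher and 684 lower of 12500. Rescaling to the same total moved the median of all genes from -0.02 to -0.46 and turned the split to 971 higher and 2303 lower, while a pseudocount of 5 left 997 genes past the rule. Without short RNAs, 743 genes were higher in dorsal skin in both layers, where independent lists would share 145, and 147 were lower in both against 25.4. These numbers for independent lists take no account of the epidermal RNA in dorsal dermis, which alone can put genes high in dorsal epidermis on both lists.

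Between Koa ear and WT dorsal epidermis, growing hair follicle genes were higher in Koa ear, 8 of 14 with 2 lower (median 1.12). Krt71 stood at 31.9 against 7.55 FPKM and Krt25 at 33.3 against 7.81 FPKM, while Shh, a signal of the follicle bulb, stood at 0.309 against 4.25 FPKM. Hoxb (-2.95), Hoxc (-2.53) and Hoxa genes (-1.68) were lower in Koa ear, with Hoxc8 at 0.0494 times its dorsal level (0.0415 to 0.0587). Sebaceous gland genes (1.25) and cell cycle genes (0.41) stood higher as lists, and stress genes (-3.12), BMP antagonists (-1.24) and dermal papilla markers (-1.45) lower. Krt2 (2591 against 9.40 FPKM), Tlx1 (39.8 against 0.0864 FPKM), Igfbp2 (124 against 3.85 FPKM) and the metalloproteinase Mmp3 (90.3 against 4.13 FPKM) led the genes higher in Koa ear, with Otx1 (17.5 against 0.253 FPKM) and Slc15a2 (10.2 against 0.0747 FPKM) behind them. Ch25h (0.344 against 175 FPKM), Epgn (2.41 against 295 FPKM) and Gm10136 (2.28 against 255 FPKM) led the genes lower, then Nr4a1 (15.5 against 915 FPKM), the vasodilator adrenomedullin (Adm, 1.10 against 99.2 FPKM), Atf3 (37.9 against 1749.8 FPKM) and Ptgs2 (2.38 against 146 FPKM). The counts were 439 higher and 1093 lower of 12489. Rescaled to the same total they were 2258 and 601 with the median of all genes at 0.53, and a pseudocount of 5 left 844 past the rule.

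Tail dermis was compared with ear and dorsal dermis for the same question of position. Sex differs along with position here, since the tail library alone has Xist and lists the Y-linked Ddx3y and Kdm5d at 0, and sex-linked genes had medians of -2.97 against ear and -3.21 against dorsal dermis. The 5' Hox genes set it apart: Hoxc12 stood at 24 FPKM in tail, 0.387 in dorsal and 0.172 FPKM in ear dermis, Hoxc11 at 16, 0.217 and 0.0386 FPKM, Hoxc13 at 14.3, 4 and 0.345 FPKM, and Hoxc10 at 10.9, 5.80 and 0.0804 FPKM. Hoxb13 stood at 20.8 FPKM in tail and was listed at 0 in both others, as was Hoxa13, at 3.79 FPKM in tail. Hoxa11 stood at 9.34 FPKM in tail and 0.0303 FPKM in dorsal dermis. Hoxc8, at 1.32 FPKM in tail, was lower than in dorsal dermis (29.5 FPKM), and Hoxc6 stood at 4.63 FPKM in tail. Melanocyte genes were higher in tail than in ear or back, among them Pmel, at 669.6 FPKM against 32.6 and 43 FPKM.

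Against ear, 7 of 8 expressed Hoxc genes were higher in tail (median 2.95), 6 of 7 Hoxb genes (2.01) and 6 of 8 Hoxa genes (1.67), with Hoxa2 lower (0.330 against 19.3 FPKM). Against dorsal dermis the Hoxc genes divided, 3 higher and 4 lower of 9 (median -0.35, above 0 and standing apart at a filter of 5 FPKM). Melanocyte genes had medians of 3.44 against ear and 2.08 against dorsal dermis, endothelial markers 1.20 and 1.44, and dermal papilla markers 0.72 and 1.08, with Crabp1 at 653 FPKM in tail, 52.7 in ear and 39.5 FPKM in dorsal dermis. Other positional factors stood apart upward (0.44 and 0.38), with the forkhead gene Foxd1 at 32.9 FPKM in tail against 2.37 and 1.14 FPKM. Myeloid markers were lower in tail (-3.33 and -3.08, Lyz2 at 26.2 FPKM against 616 and 461 FPKM). Cartilage genes were lower than in ear, 15 of 15 (-3.48).

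Basal keratinocyte markers were lower in tail (-2.33 and -4.86), and stress genes higher (4.29 and 0.89), with Fosb at 1573 FPKM in tail against 7.91 and 259 FPKM. Mast cell genes stood apart from dorsal dermis (1.58) and not from ear (-0.40). Has1, a hyaluronan synthase, stood at 222 FPKM in tail against 0.611 FPKM in ear, Ptx3 at 545 against 4.06 FPKM, and the chemokine Cxcl1 at 1009 against 9.62 FPKM. Tail values differ from the others in kind: they are rounded to 2 decimals, 222 symbols at 10 FPKM or more in the other 6 libraries are listed at 0, and pairs such as Tpt1 (2273 FPKM in tail, 6.89 in ear) and Tpt1p (0 and 4084 FPKM) exchange their levels. Counts against ear (864 higher, 3686 lower of 13666) and dorsal dermis (992 higher, 4083 lower of 14063) came with medians of all genes of -0.51 and -0.48, and median-ratio rescaling, which brought these medians to -0.04 and -0.03, gave 1733 and 2030 against ear and 1995 and 2807 against dorsal dermis. Rescaling to the same total brought the median against dorsal dermis to -0.17.

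Dermis and epidermis of the same position were compared as a check of the sorted layers. Fibroblast matrix genes were higher in dermis by a median of 7.07 in Koa ear, 7.21 in WT ear and 6.15 in WT dorsal skin. Lumican (Lum) stood at 897 FPKM in WT ear dermis and 0.555 FPKM in WT ear epidermis, and decorin (Dcn) at 7827 and 15.4 FPKM. The mesenchymal filament vimentin (Vim) stood at 1569 and 2.47 FPKM and the macrophage lysozyme Lyz2 at 616 and 0.377 FPKM. On the back Dpt stood at 891 FPKM in dermis and 2.76 FPKM in epidermis, and the cornified envelope gene Sprr4 at 26.4 and 232 FPKM. Basal keratinocyte markers were lower in dermis by smaller steps in dorsal skin, with medians of -3.07 in Koa ear, -3.99 in WT ear and -1.45 in WT dorsal skin. Krt10 stood at 94.7 FPKM in WT ear dermis and 2495 FPKM in WT ear epidermis, Krt2 at 86.3 and 3174 FPKM, and Fcgbp at 4.89 and 232 FPKM. Krt14 stood at 228 FPKM in WT ear dermis and 5518 FPKM in WT ear epidermis, and at 1082 and 4082 FPKM on the back.

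Myeloid markers (6.75), mast cell genes (6.04), pericyte (4.32), dermal papilla (2.10), melanocyte (2.84) and cartilage genes (3.93) were on the dermal side in WT ear, and cell cycle (-2.34) and growing hair follicle genes (-1.82) on the epidermal side. Positional factors other than Hox were dermal, 17 of 19 in WT ear, among them Prrx1 (106 against 0.126 FPKM) and Tbx15 (46.5 against 0.103 FPKM). In dorsal skin the Hoxb genes stood on the epidermal side (-0.88), as did the Hoxa genes (-0.82), while the Hoxc genes did not stand apart (-0.19) and Hoxc9 stood at 7.24 FPKM in dermis against 0.917 FPKM in epidermis. In Koa ear the Hoxc genes had a median of 0.71. Housekeeping genes had medians from -0.74 (dorsal dermis against epidermis) to 0.25 (dorsal against ear dermis) over all comparisons and stood apart in none. Counts were 2842 higher and 1778 lower in Koa ear, 2942 and 1989 in WT ear, and 2239 and 1149 in WT dorsal dermis, and a pseudocount of 5 lowered the totals to 2664, 2888 and 1893. Rescaled to the same total the dorsal split was 3403 and 280 with the median of all genes at 0.37, and that median was 0.14 in Koa ear and 0.23 in WT ear.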

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

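Results are given here where dermis and epidermis went opposite ways under the same contrast. Each layer has 1 library per group, so none of these differences between layers was tested.

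Between Koa and WT ear, cell cycle genes had a median of 0.21 in dermis and -0.41 in epidermis, a difference of 0.62. Myeloid markers had a median of -0.19 in dermis and 0.77 in epidermis, a difference of -0.96, but only 3 of the markers were expressed in epidermis, against 10 in dermis, and the epidermal median did not stand apart without the filter on low values. With the keratinocyte share subtracted, the dermal medians were 0.13 and -0.11 and no longer stood apart from random lists. Between WT dorsal and WT ear skin, secreted Wnt inhibitors had a median of -1.41 in dermis and 0.87 in epidermis, a difference of -2.28, over 10 and 6 expressed genes, and the epidermal median did not stand apart at a filter of 5 FPKM. The difference was 1.47 for cell cycle genes (0.65 in dermis, -0.83 in epidermis) and -1.79 for dermal papilla markers (-0.45 in dermis, 1.34 in epidermis, over 17 and 10 expressed genes). For these last lists too the dermal medians no longer stood apart after the subtraction (0.13 and -0.08).

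Of single genes, 8 passed the size rule in opposite directions in Koa ear dermis and Koa ear epidermis, each against WT ear. Spon2, a secreted matrix protein, was higher in dermis (21.0 against 6.36 FPKM) and lower in epidermis (1.36 against 4.72 FPKM), as were Defb2 and Snhg9, both listed at 0 in WT ear dermis. Chi3l1, a chitinase-like protein, was lower in dermis (27.0 against 55.7 FPKM) and higher in epidermis (14.4 against 6.42 FPKM). Btg3, an inhibitor of proliferation, was lower in dermis (0.984 against 4.59 FPKM) and higher in epidermis (3.92 against 0.869 FPKM), as were Gm7609, Kbtbd10 and Zfp457.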

How the results depend on the processing

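The alternatives without short RNAs, with the keratinocyte share subtracted and with genes above 0 in the tail library alone were chosen after the data were seen. Of the counts and covariances under the alternatives 76 stayed within 1.5 times the reported value and 18 moved further. No symbol occurs more than once, so the choice among repeated symbols changes nothing, and the counts without a filter equal those reported, since a gene under 1 FPKM in both libraries cannot pass the size rule at a pseudocount of 1.

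A pseudocount of 0.1 gave 681 genes for Koa in ear dermis (reported 380) and 680 for Koa in ear epidermis (362), and a covariance with the dorsal direction of 0.426 (no Koa effect 0.351). A pseudocount of 5 gave 185 and 170 genes for these, 1277 for dorsal against ear dermis (2674), 1050 for Koa ear against dorsal dermis (2215), 997 for dorsal against ear epidermis (2116), 844 for Koa ear against dorsal epidermis (1532), 2116 and 2516 for tail against ear and dorsal dermis (4550 and 5075), 2664, 2888 and 1893 for dermis against epidermis in Koa ear, WT ear and dorsal skin (4620, 4931 and 3388), and a covariance of 0.0925 (0.0708). By construction a larger pseudocount shrinks differences of low genes. Rescaling to the same total gave 3274 genes for dorsal against ear epidermis and 2859 for Koa ear against dorsal epidermis. Subtracting the keratinocyte share, with short RNAs left out as well, gave a covariance of 0.121 (0.0682).

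Splits between higher and lower moved by over 10 points. With equal totals they were 1580 and 1896 for dorsal against ear dermis, 1674 and 1323 for Koa ear against dorsal dermis, 971 and 2303 for dorsal against ear epidermis, 2258 and 601 for Koa ear against dorsal epidermis, 3995 and 1532 for WT ear dermis against epidermis, 3403 and 280 for the dorsal layers, and 1904 and 3550 for tail against dorsal dermis. With median ratios they were 1733 and 2030 for tail against ear and 1995 and 2807 for tail against dorsal dermis. With the keratinocyte share subtracted they were 202 and 198 for Koa in ear dermis, 1351 and 1558 for dorsal against ear dermis, and 1296 and 1210 for Koa ear against dorsal dermis.

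Some called values changed sign. Without a filter, adipocyte genes came to 0.081 in dorsal against ear epidermis and -0.20 in Koa ear against dorsal epidermis, and cartilage genes to -0.15 in tail against dorsal dermis. At a filter of 5 FPKM, sebaceous genes came to -0.73 in tail against ear and cartilage genes to -2.13 in tail against dorsal dermis. With equal totals, growth factors came to 0.18 in Koa ear against dorsal epidermis. With the keratinocyte share subtracted, over the genes still at 1 FPKM, basal keratinocyte markers came to -0.60 in Koa against WT ear dermis and hair follicle stem cell genes to -1.24 in dorsal against ear dermis. In Koa ear against dorsal dermis stem cell genes came to 0.27, fibroblast markers to -0.11 and Ch25h to 0.72. In dorsal against ear and Koa ear against dorsal dermis, Epgn came to -0.094 and 0.034, Atf3 to -0.49 and 0.80, and Ptgs2 to -0.47 and 0.34. For the basal keratinocyte markers the share was taken from these same genes, so their fall was set by the procedure. The cause of the other changes was not tested.

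Of 405 list medians, 233 lay outside the central 95% of random lists. Of these 233, 227 stayed outside at a pseudocount of 0.1, 224 at 5, 217 without a filter, 231 with median ratios and 225 with equal totals. At a filter of 5 FPKM 204 of 225 did. Medians that were inside and came to stand outside numbered 6, 11, 18, 5, 11 and 15 in these settings. With the keratinocyte share subtracted 48 of 64 stayed outside and 21 more came to. Of 394 values of named genes, most of them picked for wide differences, 378 passed the size rule. None of these 378 changed sign under the scalings. With the keratinocyte share subtracted, 7 of the 111 values past the rule did. Values under the size rule were not checked for sign. A pseudocount cannot change the sign of a single gene.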

Other observations

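Clock output genes, looked up after Ciart and Per2 had been seen to differ, had a median below 0 in Koa against WT ears, -0.96 in dermis (6 of 13 lower past the size rule) and -0.85 in epidermis (4 of 13). The repressor gene Per2 stood at 3.20 against 8.26 FPKM in dermis and 1.65 against 5.42 FPKM in epidermis, Ciart at 2.10 against 7.79 and 3.55 against 11 FPKM, and Dbp at 10.6 against 23.7 and 11.6 against 22.1 FPKM. Clock activators went the other way, with medians of 0.57 and 0.31, and Npas2 stood at 8.86 against 3.10 and 6.61 against 2.88 FPKM. In dorsal skin clock output genes were lower than in WT ear as well (-1.66 in dermis, -1.61 in epidermis), with Dbp at 2.73 and 4.13 FPKM, while Bhlhe40 was higher (136 FPKM in dorsal against 31 FPKM in ear dermis). The labels give no hour of collection, and no test of it was made.

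The summed FPKM of class I histocompatibility genes, and the level of their partner B2m, were higher in WT dorsal than in WT ear skin. Abundant genes weigh most in such a sum, and single genes can differ from it. H2-T9 was lower in dorsal than in WT ear dermis. B2m stood at 1481 against 489 FPKM in dermis and 2686 against 232 FPKM in epidermis, and the summed FPKM of 29 class I genes was 1120 in dorsal dermis, 365 in WT ear dermis, 1718 in dorsal epidermis and 332 in WT ear epidermis. Dorsal dermis holds more epidermal RNA than ear dermis, and with the keratinocyte share subtracted B2m stood at 787 against 506 FPKM and the class I sum at 778 against 367, so most of the dermal B2m difference went with that share. The interferon-induced chemokine Cxcl10 stood at 59.1 against 0.927 FPKM in dermis. The growing hair genes of Koa ear dermis stood at a median of 25.9% of Koa ear epidermis (Krt25 at 29.8%, Tchh at 32.4%), and 7 of 9 lay above the highest basal keratinocyte marker of 13.9%.

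All tests in the next paragraphs were chosen after the results they measure had been seen. The first pattern is Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc9, higher in Koa ear dermis. Epidermal cells carried over, at the highest marker share, would give at most 6.04% of the dermal level of any of the 5 genes, and the lowest lower bound of their counting intervals was 4.80 times. Dorsal dermal cells mixed into the library would move the other Hox genes as well, but 15 Hox genes high in dorsal dermis stood at a median of 0.0945% of the way from WT ear to dorsal dermis (-2.46% to 1.84%), against 7.31% to 74.4% for the 5 genes. Most of the 15 are Hoxa and Hoxb genes, whose dorsal dermal level may come from epidermal RNA, as given below. Hoxc10 and Hoxa10, both higher in dorsal dermis than in dorsal epidermis, stood at -0.542% and 0.0945% of the way. These values argue against all 3 explanations, that of mixed dorsal cells mainly by Hoxc10 and Hoxa10. An effect of the Koa allele is a hypothesis that may hold. Genotype and animal cannot be parted with 1 library each, so a difference between animals stays open and untested.

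The second pattern is Hox genes higher in dorsal than in ear dermis, where keratinocyte markers reach 26.5% to 47.6% of their epidermal level. The Hoxc genes stood in dorsal dermis at a median of 83.4% of dorsal epidermis, with 6 of 7 above the highest marker, which argues against epidermal cells carried over as the whole cause. With the median and the highest marker share subtracted from dorsal dermis, the median difference of those 7 genes was 3.19 and 3.43, that of 6 Hoxa genes 1.10 and 0.00, and that of 8 Hoxb genes 0.70 and 0.036. For the Hoxa genes (47.3%, with 3 of 6 above the highest marker, Hoxa10 at 1211%) and the Hoxb genes (45.7%, with 4 of 8 above it), taken as lists, carryover and expression in dermis cannot be told apart. Their median differences stay past the size rule at the lowest share and vanish at the highest. This does not hold for each gene alike, since Hoxa10 stood at 2.34 FPKM in dorsal dermis and 0.194 FPKM in dorsal epidermis. A difference between the positions stays open and rests on 1 library each.

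The third pattern is histocompatibility genes that differ between Koa and WT ears alike in dermis and epidermis: H2-T9, H2-T22 and H2-Q10 lower, and H2-D1 and H2-T10 higher. A strain variant at the complex (chromosome 17, 33938909 to 37483554, GRCm38) was tested on its other genes, since the H2 genes define the pattern. Of 81 such genes 1 (A930015D03Rik) passed the size rule the same way in both layers, 2.67 times the share outside (0.462% of 11260), and with 1 gene such a variant and an effect of the Koa allele cannot be told apart. Reads divided among class I paralogs cannot be told apart from a change in level either, since the summed class I FPKM was 1.73 times as high in Koa ear dermis but 1.41 times in epidermis. Mixed CD1 and C3H descent, which the strain label gives, stays open.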
